A study of Mus musculus with 13 samples.

How the data were processed

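Liver sections of male C57BL/6 mice aged 2 months were measured by Molecular Cartography, an in situ method of Resolve Biosciences that detects single transcripts of a chosen gene panel by repeated rounds of fluorescent labelling. Per the labels, 2/3 of the liver had been removed, and frozen regrown lobes were sectioned and sent to the company, which performed the assay by its own protocol. The 13 sections covered 7 time points: 0 h (2 sections), 24 h (2), 48 h (2), 72 h (2), 14 d (3), 3 mo (1) and 6 mo (1). If 2 months was the age at surgery, the 3 mo and 6 mo sections came from older mice than the 0 h sections. Age and time after surgery then cannot be told apart at 3 mo and 6 mo. Labels gave each section its time, its slide and, at 0 h, 48 h, 72 h and 14 d, a number. No label says that sections came from separate animals, so the p-values may measure only technical spread between sections.

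The authors deposited, for each section, a table of transcript counts per gene and cell, and for 12 sections a list of transcripts with their positions. Positions of the remaining 14 d section were not used here. How transcripts were decoded and how cell outlines were drawn is not given in the sources used here, nor is the length of the coordinate unit. Counts were whole numbers and the tables named 100 genes. A gene with no line in a section's table was taken as 0 counts.

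Counts were summed over the cells of each section. Both sections at 24 h carried the same slide position and no number, so they were summed to 1 library, which gave 12 libraries. Genes with at least 10 counts in at least 2 libraries were tested, 99 of 100. Each time was compared with 0 h in a single fit of all 7 times with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust quasi-likelihood F test, 5 residual degrees of freedom), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The reported error of a log2 fold change is its size divided by the square root of F. CPM values are counts divided by the TMM-scaled library total, times 1e6. TMM assumes that most genes do not change, which a chosen panel of 100 genes need not meet, and Cyp2e1 alone held 7.96% to 34.3% of the counts of a section. For a gene with 0 counts at 0 h, its fold was computed against a floor of 3 counts over the 0 h group. For genes with 1 to 3 counts at 0 h, the ratio was given with an exact 95% binomial interval. The intervals cover counting error only. A fold against the floor takes the later count as exact, so it is not a strict lower bound.

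Positions along the lobule were read from transcripts in square tiles of 400 coordinate units with at least 50 transcripts. Each tile received a central-minus-portal score, the mean z-scored log2(share x 1000 + 1) of 9 genes known from hepatocytes around the central vein (Glul, Cyp2e1, Cyp1a2, Oat, Lect2, Axin2, Lgr5, Cyp27a1, Tbx3) minus that of 6 genes known from hepatocytes around the portal vein (Gls2, Pck1, Arg1, Ass1, Cps1, Hsd17b13), always without the gene tested. For each of 62 genes with at least 500 transcripts in every section, the Spearman correlation of its share with the score across tiles was Fisher-transformed and compared with 0 h in limma 3.58.1 (robust, 4 residual degrees of freedom), with values of the 24 h sections averaged.

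Gene lists were fixed before the data were examined. Those with members in the panel were cell cycle, pericentral, periportal and mid-zonal hepatocyte, endothelial, macrophage and Kupffer, stellate, cholangiocyte, lymphocyte, Wnt pathway, Notch to Hippo signalling, growth factors, bile acid and drug metabolism, gluconeogenesis and amino acid metabolism, fetal and progenitor genes, and the central and portal genes of the score. Lists overlap, so that Lgr5, for one, counts in several of them. Lists of growth arrest, immediate early, general hepatocyte, lipid and acute phase genes had no member in the panel. Named genes followed a rule fixed at the same time. Per time these are the 10 largest rises and 10 largest falls that passed and lay beyond all 0 h sections, up to 2 further members of each list by p, and Ccnd1, Mki67, Glul, Cyp2e1, Cyp2f2, Axin2, Wnt2 and Rspo3, of which Mki67 and Cyp2f2 were not in the panel. For the position along the lobule they are the 5 largest changes each way.

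Alternatives fixed in advance were total-count scaling, DESeq2 1.42.0, scaling by cell number, other filters, all transcripts in place of those in cells, other treatment of the 24 h sections, the section number or the slide as a block, slide 1 alone, only the times compared, a fit that was not robust, other tile settings and leaving out each section. After seeing the data, 5 more were added: the 14 d sections as 1 library, scaling without Cyp2e1, and positions with Cyp2e1 left out of the totals and the score, of the totals only, or of the score only. Both fits were tested on simulated data. For the count test these were independent negative binomial draws at the fitted spread, with 24 random genes changed, as many up as down. Real contrasts need not be so balanced, so its rates may not carry over to them. For 48 h, with 99 genes, the count test called 39.2% of genes changed 2-fold, 91.2% of those changed 4-fold and 1.53% of unchanged ones, and for 3 mo it called 18.3%, 75% and 0.93%. In simulated sections, 20 of 20 genes with a slope were found with the right sign. Flat genes did not sit at 0 there: their median correlation was -0.244 with Cyp2e1 in the tile totals, and 0.125 when it was left out, so both ways of reading position are biased. The simulated tiles had the gene shares of section 1 of 0 h and fewer transcripts than the median tile of any real section. How large the bias is in the real sections was therefore not measured. Python 3.11.15 with scipy 1.17.1 was used for the other tests.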

Results

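The 7 time points held 131221 cells and 55744933 transcripts assigned to cells, from a panel of 100 genes rich in Wnt pathway genes and in hepatocyte genes that differ between the central and the portal side of the lobule. Counts in cells per section ran from 1678015 in section 2 at 24 h to 9619206 in section 2 at 14 d. Transcript density differed too, from 3615 transcripts per tile at 6 mo to 8703 in section 1 at 14 d, against 4958 and 4887 at 0 h. Slide 1 held section 1 of 0 h and 72 h, all sections of 24 h and 48 h, and 3 mo. Slide 2 held section 2 of 0 h and 72 h, and 6 mo. All 14 d sections lay on slide 3, so that slide and time cannot be told apart at 14 d. Total-count scaling moved the median gene up against TMM scaling by 0.42 at 24 h, 0.67 at 48 h, 0.43 at 72 h, 0.74 at 14 d, 0.62 at 3 mo and 0.28 at 6 mo in log2, so that each count of higher and lower genes has the total-count value beside it.

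Sections at 0 h served as the baseline, and the 2 of them differed by more than 1 in log2(CPM + 1) in 21 genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 3117 CPM in section 1 and 147 CPM in section 2, and the Wnt receptor gene Fzd8 at 424 and 82.0 CPM. G6pc, which encodes glucose-6-phosphatase, went the other way, from 1.08% of the counts of section 1 to 6.75% of those of section 2. The 21 genes also include Ccne1 (247 and 45.0 CPM), Csad (390 and 84.8), Lect2 (2503 and 807) and Oat (6750 and 3313). Sulf2 (31.3 and 7.64) and Cldn7 (39.2 and 14.1) are among them as well. Changes of these genes against 0 h rest on an uneven baseline. Over 99 genes the root mean square log2 difference between the 0 h sections was 0.99, against 0.66 at 48 h, 0.54 at 72 h and 0.32 to 0.40 at 14 d. Every pair of sections of the same time differed by more than sampling noise, with a chi-square per degree of freedom of at least 205.

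At 24 h after surgery Ccnd1 rose by 1.99 ± 0.31 in log2 (SE, 1 library of 2 sections against n = 2), from 2133 to 8452 CPM, and Ccne1 by 2.98 ± 0.68. The rise of Ccne1 ran from 2.21 to 4.85 over the alternatives. The 24 h library was assumed to vary like the other times, since its own spread was not measured. Pericentral genes went both ways: Gstm3 (3.45 ± 0.29), Oat (2.49 ± 0.48), Lect2 (1.78 ± 0.52), Lgr5 (1.77 ± 0.49) and Cldn2 (1.41 ± 0.41) rose, whereas the drug-metabolizing Cyp2e1 fell by 1.79 ± 0.32 and Cyp27a1 fell by 1.10 ± 0.36. Cyp8b1, which sets the make-up of bile acids, fell by 2.61 ± 0.53, from 3614 to 590 CPM. The complement gene C8b fell by 1.20 ± 0.34, Pon1 fell by 1.16 ± 0.32, Csad fell by 2.62 ± 0.77 and Wnt10a fell by 1.45 ± 0.51. Without section 1 of 0 h Csad stood at -0.97. Gstm2 (2.29 ± 0.31), a relative of Gstm3, and the tight junction gene Cldn7 (2.04 ± 0.57) rose. Ccna1, with 16 counts against 0, was 7.77-fold above the floor of 3 counts, and Fzd2, with 38 counts against 1, had a ratio of 55.4 (9.35 to 2243).
Of the lists, 2 of 3 cell cycle genes rose (2 adjusted over the list alone), with Ccnb1 at 0.94 ± 1.57. Of 16 pericentral genes 5 rose and 2 fell (6 and 2 adjusted over the list alone). Of 12 periportal genes 0 passed in edgeR (0 adjusted over the list alone), 1 had an unadjusted p under 0.05 and DESeq2 called 1, Hsd17b13 standing at -0.92 ± 0.35. Of 36 Wnt pathway genes 6 rose and 1 fell (6 and 0 adjusted over the list alone), among them Wnt5a (1.46 ± 0.44) and the scarce Wnt7b (2.10 ± 0.62), Wnt3a (2.10 ± 0.61) and Wnt7a (1.82 ± 0.56). Of 5 bile acid and drug genes 3 fell (3 adjusted over the list alone), with Cyp1a2 at 0.52 ± 0.33 and Cyp7a1 at -2.05 ± 1.98. Of 9 gluconeogenesis and amino acid genes only Oat passed (1 adjusted over the list alone), with G6pc at -1.68 ± 1.32.
In all, 15 genes were higher and 7 lower at 24 h by edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, the smallest adjusted p being 2.12e-08. Total-count scaling gave 20 and 2, the latter Cyp8b1 and Cyp2e1. With the slide as a block 6 and 2 passed, the rises of Fzd2, Gstm3, Ccne1, Oat, Gstm2 and Ccnd1 and the falls of Csad and Cyp8b1, and the other calls ended, among them that of Cyp2e1, which stood at -1.80 in log2 (adjusted p 0.0696 in edgeR, Benjamini-Hochberg). Slide 1 alone gave 8 and 5, and there too the call of Cyp2e1 ended (-1.80, 0.123). Relative to cell number 18 and 2 passed, the falls being those of Cyp8b1 and Cyp2e1. With the 14 d sections as 1 library, an alternative chosen after seeing the data that leaves fewer libraries to measure spread, 9 and 2 passed, and the calls of Lgr5, Cldn2, Wnt3a, Wnt5a, Wnt7a, Wnt7b, Cyp2e1, C8b, Pon1, Cyp27a1 and Wnt10a ended. Without section 1 of 0 h, 24 genes were higher. The lower count was 12 without section 2 of 0 h, 14 without section 1 of 24 h, and 15 and 13 without section 1 or 2 of 48 h. Some edgeR calls ended when a single section was left out (adjusted p, Benjamini-Hochberg): Csad (0.0828) and Cyp27a1 (0.0773) without section 1 of 0 h, Cyp27a1 also without section 1 of 14 d (0.051), Lect2 without section 2 of 72 h (0.0507), and Wnt10a without 7 of the sections (up to 0.205 without section 2 of 0 h).

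By 48 h Gstm3, a glutathione S-transferase gene, had risen by 4.26 ± 0.28 in log2 (n = 2 against 2), from 2063 ± 144 to 39468 ± 1769 CPM (SD). Its close relatives Gstm1 (2.47 ± 0.45) and Gstm2 (2.34 ± 0.27) rose as well, although how the probes tell such similar sequences apart is not given in the sources used here. Ccne1 rose by 3.09 ± 0.62 and Ccnd1 by 2.09 ± 0.27. Cyp8b1 fell by 4.0 ± 0.42, from 3614 ± 858 to 226 ± 48.9 CPM, and Cyp2e1 fell by 2.53 ± 0.25. Ccna1, with 38 counts against 0, was 9.1-fold above the floor of 3 counts.
Further rises were those of Sulf2 (2.73 ± 0.71), Wnt3a (1.72 ± 0.54), Wnt7a (1.71 ± 0.49), Cldn2 (1.54 ± 0.36) and Lect2 (1.36 ± 0.45). Sulf2 stood at 1.45 without section 2 of 48 h, Wnt3a at 0.89 without section 1 of 48 h and Lect2 at 0.69 without section 2 of 0 h. Smaller falls included Wnt10a (-1.34 ± 0.40), Prodh (-1.05 ± 0.30), Hpd (-0.90 ± 0.24), C8b (-0.97 ± 0.27), C6 (-0.93 ± 0.29), Pon1 (-0.91 ± 0.25), Cyp27a1 (-0.78 ± 0.28) and the urea cycle gene Cps1 (-0.82 ± 0.24). The leukocyte gene Ptprc fell by 1.01 ± 0.35 and the macrophage gene Lyz2 fell by 0.82 ± 0.28. Of 3 cell cycle genes 2 rose (3 adjusted over the list alone), Ccnb1 standing at 2.66 ± 1.13. Of 16 pericentral genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), of 12 periportal genes 1 fell (1 adjusted over the list alone), and of 9 gluconeogenesis and amino acid genes 1 fell (1 adjusted over the list alone), in both lists Cps1. Of 5 bile acid and drug genes 3 fell (3 adjusted over the list alone). Of 36 Wnt pathway genes 2 rose and 1 fell by edgeR. Adjusted over the list alone 0 passed, while 9 had an unadjusted p under 0.05 and DESeq2 called 3 higher and 1 lower.
The 48 h contrast held 11 higher and 12 lower genes in edgeR's quasi-likelihood test (smallest adjusted p 2.2e-10, Benjamini-Hochberg), against 40 and 2 with total-count scaling. Falls other than those of Cyp8b1 and Cyp2e1 were lost with that scaling and relative to cell number, where 32 and 2 passed. The 14 d sections as 1 library gave 9 and 9, ending the calls of Wnt3a, Wnt7a, Cps1, Hpd and Ptprc, and only the times compared gave 8 and 3, with the falls of Cyp8b1, Cyp2e1 and Prodh. With the slide as a block 5 and 3 passed, the rises of Gstm3, Gstm1, Gstm2, Ccne1 and Ccnd1 and the falls of Cyp8b1, Cyp2e1 and C6, and the other calls ended. Slide 1 alone gave 5 and 5, the same 5 rises and the falls of Cyp8b1, Cyp2e1, C6, Prodh and Fzd8. Leaving out section 1 of 0 h gave 22 higher genes, and leaving out section 2 of 48 h gave 7 lower ones. Without section 2 of 48 h the edgeR calls of Sulf2, Wnt7a, Wnt10a, Ptprc, Hpd, Cps1, Lect2 and Lyz2 ended (adjusted p 0.0502 for Wnt7a to 0.303 for Lect2, Benjamini-Hochberg). Without section 2 of 0 h those of Sulf2, Wnt3a, Wnt10a, Ptprc, Cps1, Lect2 and Lyz2 did (0.0694 for Lyz2 to 0.147), and that of Wnt3a also without section 1 of 48 h (0.215). Lect2 lost its call without 8 of the sections, Ptprc without 6, and Lyz2 and Cyp27a1 without 5 each (Cyp27a1 up to 0.079, without section 1 of 14 d).

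**Figure D1:**
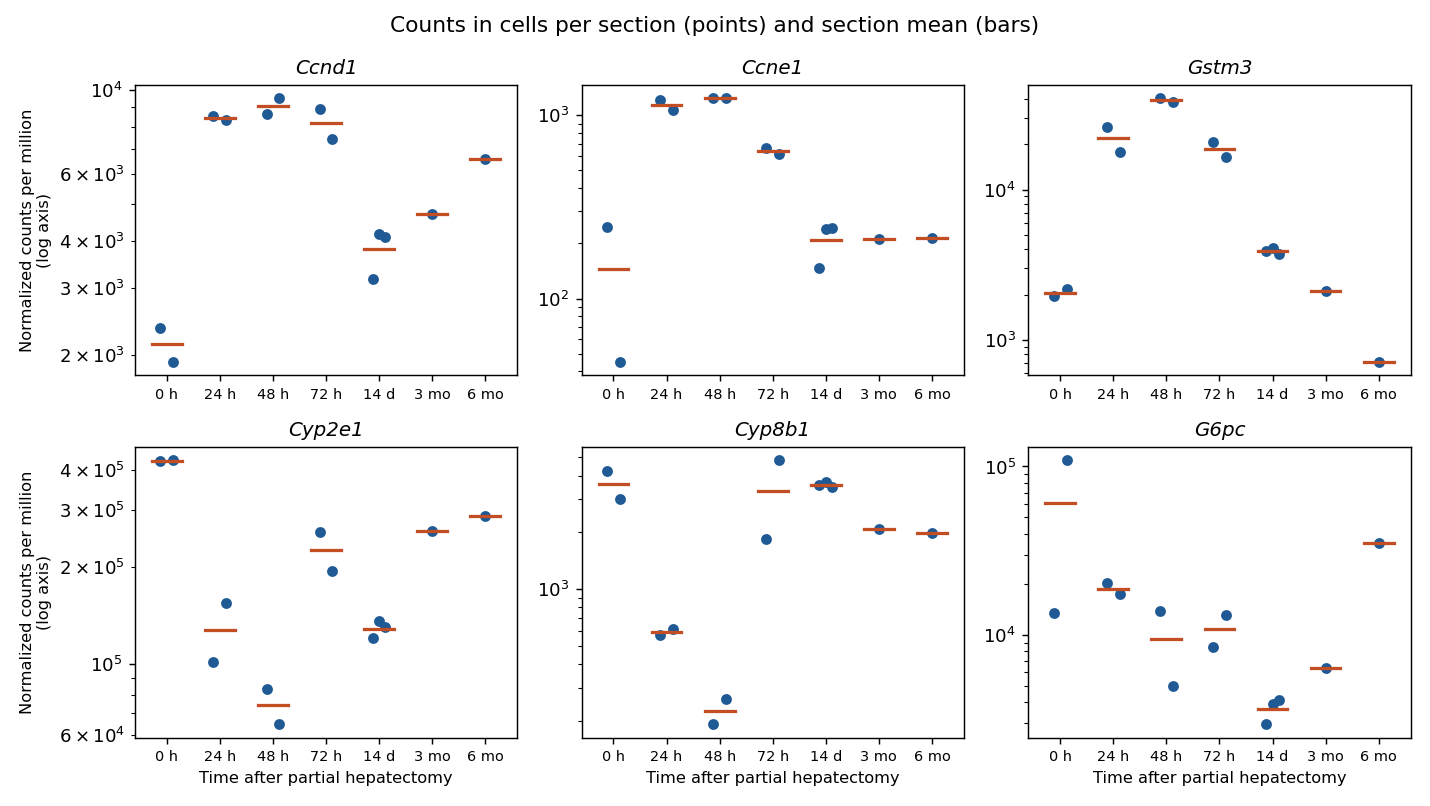
Normalized counts (CPM) on log axes for 6 genes at each time after partial hepatectomy; points are sections and bars their mean. Ccnd1 averaged 2133 at 0 h and 9077 at 48 h, Gstm3 2063 and 39468, whereas Cyp8b1 went from 3614 to 226, and the 2 sections of G6pc at 0 h lie far apart.

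At 72 h Gstm3 (3.17 ± 0.26), Gstm1 (2.12 ± 0.44), Gstm2 (1.37 ± 0.26), Ccnd1 (1.94 ± 0.27) and Ccne1 (2.12 ± 0.60) were above 0 h (n = 2 against 2). Cyp8b1 stood at -0.12 ± 0.38, at 3325 ± 2106 CPM against 3614 ± 858 (SD). C8b fell by 1.31 ± 0.27, Cyp1a2 by 1.02 ± 0.28, C6 by 0.99 ± 0.29, Cyp2e1 by 0.93 ± 0.24, Cyp27a1 by 0.83 ± 0.28 and Cps1 by 0.74 ± 0.24. Relative to cell number all 6 of these calls ended, with C8b at -0.35, Cyp1a2 at -0.14, C6 at -0.09, Cyp2e1 at 0.013, Cyp27a1 at 0.086 and Cps1 at 0.21. Wnt7a (2.10 ± 0.49), Wnt16 (1.88 ± 0.57) and Wnt5b (1.19 ± 0.39) rose, and Ccna1, with 29 counts against 0, was 7.33-fold above the floor of 3 counts.
Of 3 cell cycle genes 2 rose (2 adjusted over the list alone), of 16 pericentral genes 1 rose and 3 fell (2 and 4 adjusted over the list alone), and of 36 Wnt pathway genes 3 rose (1 adjusted over the list alone). Of 5 bile acid and drug genes 3 fell (3 adjusted over the list alone). Cps1 was the 1 of 12 periportal genes that fell in edgeR (0 adjusted over the list alone, where 2 higher and 1 lower had an unadjusted p under 0.05 and DESeq2 called 2 lower), and the 1 of 9 gluconeogenesis and amino acid genes that fell (2 adjusted over the list alone). Glul, the glutamine synthetase gene of the innermost central cells, stood at -1.06 ± 0.35 and G6pc at -2.49 ± 1.05, neither of which passed.
By edgeR's quasi-likelihood test 9 genes were higher and 6 lower at 72 h (smallest adjusted p 1.72e-08, Benjamini-Hochberg), against 26 and 1 (C8b) with total-count scaling and 38 and 0 relative to cell number. The 14 d sections as 1 library gave 8 and 4, ending the calls of Wnt16, Wnt5b, Cyp2e1, Cyp27a1 and Cps1, and only the times compared gave 5 and 1, the fall being that of C8b. With the slide as a block 6 and 2 passed, the rises of Gstm3, Gstm1, Gstm2, Ccnd1, Ccne1 and Wnt7a and the falls of C8b and C6, and on slide 1 alone 4 and 1 did, Gstm3, Gstm1, Gstm2 and Ccnd1 as the higher genes and Cyp1a2 as the lower one. DESeq2 gave 12 and 11. Without section 1 of 0 h the counts were 19 and 10, and the lower count was 13 without section 2 of 48 h, 3 without section 1 of 72 h and 1 without section 2 of 72 h. Without section 2 of 72 h the edgeR calls of Ccne1 (adjusted p 0.117), Wnt5b (0.165), Cyp1a2 (0.0729), C6 (0.197), Cyp2e1 (0.126), Cyp27a1 (0.41) and Cps1 (0.126) ended. Without section 1 of 72 h those of Ccne1 (0.0943), Wnt16 (0.113), Wnt5b (0.106), Cyp1a2 (0.0957), Cyp2e1 (0.121) and Cps1 (0.238) did, and without section 2 of 0 h those of Ccna1 (0.0532), Wnt16 (0.0865), Wnt5b (0.133) and Cps1 (0.136), while that of Cyp1a2 also ended without section 1 of 0 h (0.0704). Cps1 lost its call without 9 of the sections, Wnt5b without 6, Cyp27a1 without 5 and Ccne1 without 4.

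At 14 d 8 of 36 Wnt pathway genes rose and 2 fell. Fzd2 went from 1 count to 1749, a ratio of 336 (60.2 to 13278), and Wnt16 (2.62 ± 0.54), Wnt11 (2.56 ± 0.52), Wnt7a (2.10 ± 0.47), Wnt2b (2.09 ± 0.49), Fzd1 (1.23 ± 0.34) and Wnt5a (1.08 ± 0.35) rose too (n = 3 against 2). Most of these were scarce, Wnt7a averaging 34.2 ± 8.78 CPM against 7.97 ± 0.66 (SD). The Wnt-dampening gene Znrf3 fell by 1.44 ± 0.28 and the co-receptor gene Lrp6 by 0.81 ± 0.24, though relative to cell number they stood at 0.019 and 0.69. Ccnd1 rose by 0.84 ± 0.24 and Gstm3 by 0.93 ± 0.23, with Ccne1 at 0.52 ± 0.53.
C6 fell by 2.80 ± 0.27 and was also called lower relative to cell number, at -1.36. Cyp1a2 fell by 1.94 ± 0.25, Cyp2e1 by 1.74 ± 0.22 and Elovl2 by 1.66 ± 0.24, but relative to cell number they stood at -0.48, -0.24 and -0.20 and were not called. Glul, Cpox, C8b, Cps1 and Arg1 were not lower relative to cell number. Glul fell by 1.57 ± 0.32 (0.0024 relative to cell number), Cpox by 1.32 ± 0.25 (0.13), C8b by 1.21 ± 0.24 (0.33), Cps1 by 1.08 ± 0.22 (0.46) and Arg1 by 1.06 ± 0.22 (0.46). Transcripts per tile at 14 d were 8703 and 8357. G6pc fell by 4.06 ± 0.95, with 0 h sections that differed widely. Ccna1 was 4.61-fold above the floor of 3 counts and Fzd10 had a ratio of 10.8 (3.62 to 52.7). Rises were also seen for Sulf2 (2.85 ± 0.68), Gstm1 (2.07 ± 0.42), Gstm2 (1.48 ± 0.25) and Cldn7 (1.92 ± 0.47).
Adjusted over the list alone the Wnt pathway counts were 8 and 2 as well. Of 16 pericentral genes 1 rose and 4 fell (2 and 4 adjusted over the list alone), and of 12 periportal genes 3 fell (3 adjusted over the list alone). Of 3 cell cycle genes 1 rose (1 adjusted over the list alone), of 5 bile acid and drug genes 2 fell (2 adjusted over the list alone), and of 9 gluconeogenesis and amino acid genes 4 fell (1 rose and 4 fell adjusted over the list alone).
In edgeR's quasi-likelihood test 15 genes were higher and 13 lower at 14 d (smallest adjusted p 1.86e-07, Benjamini-Hochberg), against 37 and 5 with total-count scaling, the latter C6, Cyp1a2, Cyp2e1, Elovl2 and G6pc, and 75 and 2 relative to cell number. With the 3 sections as 1 library, chosen after seeing the data because they lay so close together, 10 and 4 passed. The calls of Ccnd1, Gstm3, Fzd1, Fzd10, Wnt5a, Cyp2e1, Znrf3, Lrp6, Cpox, C8b, Cps1, Arg1, G6pc and Vtn ended there, so that neither fall in the Wnt pathway list was left. Leaving out section 1 of 0 h gave 26 higher, and leaving out section 2 of 0 h gave 23 lower. Calls in edgeR that ended were those of G6pc without any 1 of the 14 d sections (adjusted p 0.0815 to 0.0888, Benjamini-Hochberg), Fzd10 without section 1 of 0 h (0.0677), Lrp6 without section 1 of 14 d (0.0667), Wnt5a without section 2 (0.0573) or section 3 (0.0847) of 14 d, and Vtn without section 2 of 0 h (0.182), section 1 of 72 h (0.0643) or section 1 of 14 d (0.0754). Vtn stood at -0.89 with TMM scaling and at 0.65 relative to cell number.

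By root mean square distance in log2, the single section at 3 mo lay nearest to 0 h of all later sections. It stood at 0.61 from section 1 of 0 h, which shared its slide, and 1.02 from section 2. Chi-square per degree of freedom did not give the same order for section 2. There 3 mo stood at 1307 from section 1 and 6132 from section 2, and 6 mo, on slide 2, at 4326 and 1925. Ccnd1 stood at 1.14 ± 0.31, Lrat at 1.06 ± 0.38, Axin2 at -1.22 ± 0.51, Cyp2e1 at -0.73 ± 0.30 and Glul at -0.94 ± 0.45 in log2 (1 section against n = 2). By edgeR's quasi-likelihood test 0 genes passed in either direction, the smallest adjusted p being 0.0978 (Benjamini-Hochberg), 3 higher and 9 lower had an unadjusted p under 0.05, and DESeq2 called Ccnd1 higher and G6pc lower. Adjusted over the list alone, Ccnd1 was called among 3 cell cycle genes, 1 higher and 0 lower. In the pericentral, periportal, Wnt pathway, bile acid and gluconeogenesis lists 0 passed in edgeR, also 0 adjusted over the list alone, with 2, 2, 2, 1 and 1 members at an unadjusted p under 0.05, and DESeq2 called 1 in the periportal and 1 in the gluconeogenesis list, both times G6pc. Total-count scaling gave 1 higher (Ccnd1) and 0 lower. With the slide as a block, and on slide 1 alone, 0 and 0 passed. Without section 1 of 0 h, 15 genes were higher and 9 lower, 2 were higher without section 1 of 72 h, and 1 was without section 1 of 24 h, either section of 48 h, or 6 mo. A lone section was assumed to vary like the other times, and simulated 2-fold changes were called in 18.3% of cases.

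At 6 mo, too, a lone section was assumed to vary like the other times, and its own spread was not measured. Rgn, a calcium-binding protein gene of hepatocytes, fell by 2.06 ± 0.40, Cyp27a1 by 1.61 ± 0.37, Cpox by 1.61 ± 0.37, Gstm3 by 1.54 ± 0.32, Gstm2 by 1.47 ± 0.34, Pon1 by 1.36 ± 0.32 and Igf1, a hepatic growth factor gene, by 1.34 ± 0.35 (1 section against n = 2). Ccnd1 rose by 1.62 ± 0.31, from 2133 to 6561 CPM. Slc16a10 (3.43 ± 0.66), Fzd6 (2.39 ± 0.54), Wnt10a (1.47 ± 0.46), the biliary and progenitor gene Sox9 (1.37 ± 0.43), Igfbp2 (1.11 ± 0.31) and the macrophage gene Lyz2 (1.06 ± 0.33) rose, with Adgre1 at -0.15 ± 0.45. Fzd2 had 21 counts against 1, a ratio of 46.3 (7.44 to 1913).
Other calls at 6 mo were the rises of Wnt8a (2.76 ± 0.93), Wnt16 (1.85 ± 0.66) and Fzd9 (1.85 ± 0.61), and the falls of Uqcrh (-1.45 ± 0.42), C6 (-1.23 ± 0.38), C8b (-1.13 ± 0.34), Cyp1a2 (-1.12 ± 0.36) and Arg1 (-0.90 ± 0.32). Of 16 pericentral genes 4 fell (4 adjusted over the list alone), of 12 periportal genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), and of 36 Wnt pathway genes 5 rose (2 adjusted over the list alone). Wnt8a is not a member of the Wnt pathway list and is not in that count. Of 3 cell cycle genes 1 rose (1 adjusted over the list alone) and of 5 bile acid and drug genes 2 fell (2 adjusted over the list alone). Of 9 gluconeogenesis and amino acid genes 1 fell in edgeR (0 adjusted over the list alone, where 2 had an unadjusted p under 0.05 and DESeq2 called 1).
In edgeR's quasi-likelihood test 11 genes were higher and 12 lower at 6 mo (smallest adjusted p 0.00179, Benjamini-Hochberg), against 16 and 7 with total-count scaling and 17 and 18 by DESeq2. The section lay on slide 2, and with the slide as a block 1 and 6 passed, Ccnd1 as the higher gene and Rgn, Cyp27a1, Cpox, Gstm3, Gstm2 and Pon1 as the lower ones. The 14 d sections as 1 library left 4 and 2, the rises of Ccnd1, Slc16a10, Fzd6 and Fzd2 and the falls of Rgn and Cyp27a1, so that the calls of Cpox, Gstm3, Gstm2, Pon1, Igf1, Uqcrh, Sox9 and Lyz2, among others, ended. Relative to cell number 5 and 3 passed, the rises of Ccnd1, Slc16a10, Fzd6, Fzd9 and Fzd2 and the falls of Rgn, Gstm3 and Pon1. The counts were 20 higher without section 1 of 0 h and 22 lower without section 2 of 0 h. Leaving out section 1 of 0 h ended the edgeR calls of Wnt8a (adjusted p 0.0641), Wnt10a (0.0585), C6 (0.0576), Cyp1a2 (0.233) and Arg1 (0.0627), and leaving out section 1 of 72 h those of Wnt10a (0.0588), Igfbp2 (0.0555), C8b (0.0588), Cyp1a2 (0.0588) and Arg1 (0.0901). Arg1 lost its call without 10 of the sections, Wnt8a without 5 (up to 0.0754), Wnt16 without 4 (up to 0.0839) and Igfbp2 without 3 (up to 0.0601), while C8b also did without section 1 of 48 h (0.0572), Cyp1a2 without section 2 of 48 h (0.0579) and Fzd9 without section 2 of 14 d (0.0575).

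Lists of other liver cells and of signalling had few calls. Of 4 endothelial genes 0 passed in edgeR at any time (0 adjusted over the list alone), with 1 at an unadjusted p under 0.05 and 1 called by DESeq2, both times at 14 d, where Pecam1 stood at 0.67 ± 0.26. Wnt2, which endothelial cells of the central vein secrete, stood at 0.80 ± 0.45 at 24 h and 0.31 ± 0.37 at 48 h. Of 2 macrophage genes Lyz2 fell at 48 h and rose at 6 mo (also adjusted over the list alone, with 1 lower at 72 h besides), and at the other times 0 passed in edgeR. There Lyz2 alone had an unadjusted p under 0.05 and a DESeq2 call, at 72 h (-0.73 ± 0.28). Sox9, the sole cholangiocyte gene, rose at 6 mo. Adjusted over the list alone it was called at 72 h (0.83 ± 0.37), 14 d (0.87 ± 0.34) and 6 mo, and by DESeq2 at 14 d and 6 mo. Ptprc, the sole lymphocyte gene, fell at 48 h, and adjusted over the list alone, and by DESeq2, it was called at 24 h (-1.04 ± 0.45) as well. Lrat, the stellate gene, passed at 0 of the times in edgeR or DESeq2, and adjusted over the list alone at 72 h (0.79 ± 0.32), 14 d (-0.63 ± 0.29) and 3 mo (1.06 ± 0.38), which for a list of 1 gene is an unadjusted p under 0.05.
Igf1, the sole growth factor gene, fell at 6 mo, and adjusted over the list alone, and by DESeq2, it was called at 14 d (-0.59 ± 0.24) as well. Yap1 of Notch to Hippo signalling passed at 0 of the times in edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in DESeq2, from -0.52 ± 0.33 at 3 mo to -0.09 ± 0.26 at 48 h. Of 2 mid-zonal genes Cyp8b1 fell at 24 h and 48 h and Igfbp2 rose at 6 mo (1 adjusted over the list alone at each, and 1 at 72 h, Igfbp2 at 0.71 ± 0.27), and 0 passed in edgeR at 72 h, 14 d and 3 mo, where 1, 0 and 0 had an unadjusted p under 0.05 and DESeq2 called 0. Of 2 fetal and progenitor genes Lgr5 rose at 24 h and Sox9 at 6 mo (1 adjusted over the list alone at 24 h, 14 d and 6 mo). At the other times 0 passed in edgeR, with 1 at an unadjusted p under 0.05 at 72 h and 14 d, and 1 called by DESeq2 at 14 d.
Among the 9 central genes of the score, 3 rose and 2 fell at 24 h, 1 and 2 at 48 h, 0 and 3 at 72 h, 0 and 3 at 14 d, 0 and 0 at 3 mo, and 0 and 2 at 6 mo in edgeR. Adjusted over the list alone these were 3 and 2, 1 and 2, 0 and 4, 1 and 3, 0 and 0, and 0 and 2. Of the 6 portal genes 0, 1, 1, 2, 0 and 1 fell and 0 rose, and adjusted over the list alone 0, 1, 1, 2, 0 and 0 fell. At an unadjusted p under 0.05 stood 2 central and 1 portal genes at 3 mo and 1 portal gene at 24 h and at 6 mo, and DESeq2 called 0 central and 0 portal genes at 3 mo and 1 portal gene at 24 h and at 6 mo.

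Over all 7 times 65 of 99 genes differed, led by Gstm3 (adjusted p 1.07e-11, edgeR quasi-likelihood F test of 6 coefficients, Benjamini-Hochberg), Fzd2, Gstm2 and Cyp2e1. With the 14 d sections as 1 library 39 did.

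Positions along the lobule address the spatial part of the design. Cyp2e1 tracked the central side in every section, with correlations of 0.923 to 0.966, and Pck1 the portal side, with -0.967 to -0.883. Not every gene of the score followed it so closely. The central gene Glul ran from 0.16 to 0.54 and the portal gene Cps1 from -0.81 to -0.33. With Cyp2e1 left out of the totals and the score, Cps1 stood at -0.244 and -0.016 at 0 h, and at 0.021 and 0.096 at 14 d. The central lean of Cyp1a2 became weaker at 24 h, its correlation going from 0.901 to 0.299 (change in Fisher z -1.17 ± 0.17, mean of 2 sections against n = 2). With Cyp2e1 left out of the totals and the score, Cyp1a2 went from 0.932 to 0.572 and so stayed central. Fads1, a fatty acid desaturase gene, moved to the central side, from -0.769 at 0 h to 0.569 at 24 h (1.67 ± 0.20) and 0.548 at 48 h (1.66 ± 0.16). Gstm2, already central at 0 h, followed the score more closely at 48 h, from 0.713 to 0.916 (0.67 ± 0.13). Its transcripts rose from 7202 and 5765 in the 0 h sections to 40613 and 69762 in those of 48 h. Whether more counts alone tightened its correlation was not tested. The portal lean of G6pc became weaker at 3 mo, from -0.874 to -0.535 (0.76 ± 0.17, 1 section).
Cyp1a2 at 24 h, Fads1 and Gstm2 at 48 h and G6pc at 3 mo were called both with all transcripts and with Cyp2e1 left out of the totals and the score, an alternative added after seeing the data. With Cyp2e1 left out, Fads1 was at 0.244 at 0 h, 0.776 at 24 h (change 0.79, adjusted p 0.103 in limma, not passed) and 0.774 at 48 h, so its portal lean at 0 h depended on Cyp2e1. At 3 mo that reading went the other way, with Fads1 at -0.716 (change -1.15, adjusted p 0.015, limma, Benjamini-Hochberg), and C6 (-0.73, 0.015) and Epas1 (-0.57, 0.0352) also became more portal (1 section). With all transcripts these 3 changed by -0.57, -0.72 and -0.40 and were not called. Fads1 stood at -0.403 at 6 mo (change -0.68, not passed). With Cyp2e1 left out of the totals only, also chosen after seeing the data, Cyp1a2 at 24 h (-1.11, adjusted p 0.0141) and Fads1 (0.83, 0.0331) and Gstm2 (0.63, 0.033) at 48 h passed in limma after Benjamini-Hochberg adjustment and G6pc at 3 mo did not (0.74, 0.0512). Over the alternatives other than leaving out a section, Cyp1a2 kept its call in 13 of 13, Fads1 in 14 of 14 and Gstm2 in 13 of 14. Gstm2 lost it with Pearson correlation (-0.021, adjusted p 0.863, limma), where its change had the opposite sign. Changes were smaller with cells in place of tiles and with thinned tiles: Cyp1a2 -0.59 and -0.25, Fads1 0.61 and 0.28, Gstm2 0.35 and 0.22. These tallies, like that of G6pc, include the setting used to select the genes, where the call held by choice. A minimum of 2000 transcripts and the 24 h sections as 2 samples left each change at its main size. G6pc kept its call in 6 of 13. It ended with tiles of 200 or 800 units, thinned tiles, cells in place of tiles, the slide as a block, Pearson correlation and Cyp2e1 left out of the totals only (adjusted p up to 0.421). G6pc at 3 mo also lost its limma call without section 2 of 0 h (0.67, adjusted p 0.131, Benjamini-Hochberg) and without either section of 72 h (0.76, 0.0614).
Other changes were called with all transcripts but not with Cyp2e1 left out of the totals and the score. More central and more portal name the direction of the change only. Vtn (-0.924 to -0.757) and C8b (-0.846 to -0.522) at 24 h, Gstm3 at 72 h (0.793 to 0.303), and G6pc (-0.874 to -0.654) and Axin2 (0.666 to 0.401) at 14 d kept their side, with a weaker correlation. Others changed sign, among them Cpt2 at 24 h (-0.352 to 0.591) and Lrp5 at 48 h (-0.156 to 0.616). At 24 h Cpt2 (1.06), Alad (0.83), C8b (0.69) and Vtn (0.64) became more central, and at 48 h Lrp5 (0.88), Cyp27a1 (0.81), Znrf3 (0.79) and Alad (0.74) did. At 72 h Fads1 (0.71) and Cyp8b1 (0.65) became more central and Gstm3 (-0.78) and Cpox (-0.51) more portal. At 14 d Cyp8b1 (0.70), G6pc (0.58), C8b (0.55), Vtn (0.51) and Fads1 (0.51) became more central, and Cldn2 (-0.62), Gstm3 (-0.57) and the Wnt target Axin2 (-0.37) more portal. At 3 mo Prodh (-0.67) and Lrat (-0.58) became more portal. Each of these at 14 d ended in limma without either 14 d section (adjusted p 0.0556 or more, Benjamini-Hochberg), those of Prodh and Lrat ended without section 2 of 0 h (0.173 each), those of Fads1 (0.326), Cyp8b1 (0.359) and Cpox (0.302) at 72 h without section 2 of 72 h, and that of Vtn at 24 h without section 1 of 0 h (0.0795).
In limma after Benjamini-Hochberg adjustment, 10 of 62 genes became more central and 1 more portal at 24 h, 24 and 0 at 48 h, 2 and 2 at 72 h, 9 and 3 at 14 d, 1 and 2 at 3 mo, and 0 and 0 at 6 mo, where 14 had an unadjusted p under 0.05 and no other tool was run. With Cyp2e1 left out the counts were 0 and 1, 2 and 0, 0 and 0, 0 and 0, 1 and 3, and 0 and 0. With the slide as a block 12, 23, 5, 0 and 0 genes passed at 24 h, 48 h, 72 h, 3 mo and 6 mo. Without section 2 of 0 h the counts were 25 at 24 h, 20 at 72 h, 34 at 14 d, 0 at 3 mo and 19 at 6 mo. Without section 1 of 0 h they were 7, 2, 7, 7 and 5 at those times. Without either section of 72 h 6 passed at 24 h and 0 at 3 mo, without section 2 of 48 h 15 passed at 48 h, without section 2 of 72 h 1 passed at 72 h, and without either 14 d section 0 passed at 14 d.

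**Figure D2:**
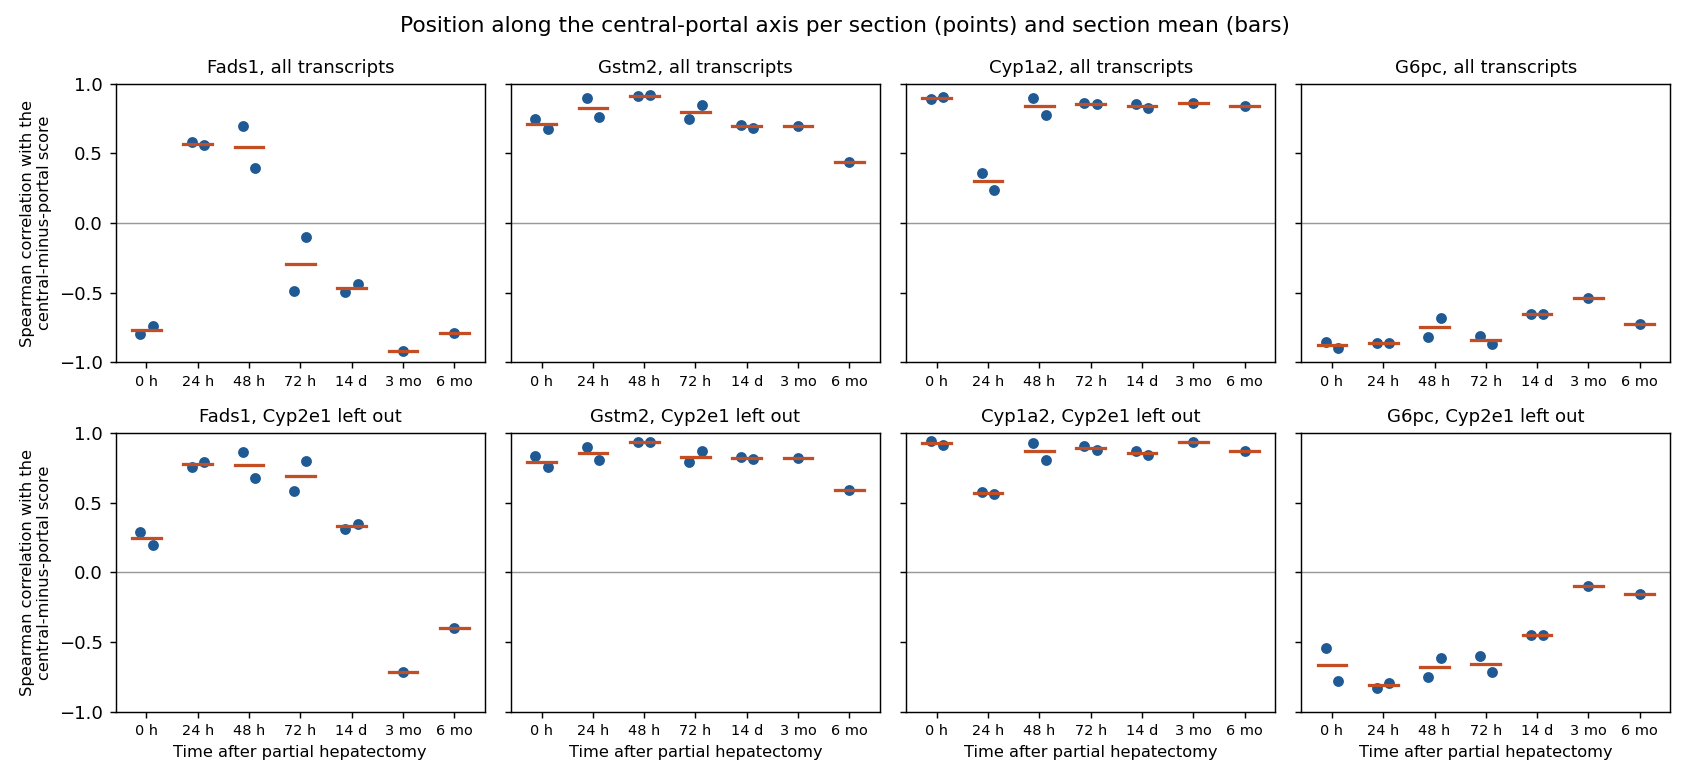
Spearman correlation across tiles of 4 genes with the central-minus-portal score at each time, with all transcripts (upper row) and with Cyp2e1 left out (lower row); points are sections and bars their mean. Fads1 averages -0.769 at 0 h and 0.548 at 48 h in the upper row, and 0.244 and 0.774 in the lower row.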

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

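The tests of the slides and of Cyp2e1 were chosen after the results had been seen, and both tests of the share in cells were written before.

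Gene positions differed between times for 4 genes by the limma test of the change, with Cyp2e1 and with it left out of totals and score: Cyp1a2 at 24 h (-1.17 in Fisher z), Fads1 at 48 h (1.66), Gstm2 at 48 h (0.67) and G6pc at 3 mo (0.76). The call of G6pc is weak, since it held in 6 of 13 alternatives, including the setting used to select it, and without 8 of 11 sections. That of Gstm2 ended with Pearson correlation (-0.021). The wider pattern is that 24 genes leaned more to the central side at 48 h than at 0 h. The share of Cyp2e1 in the tile totals may account for most of it: the median change over these genes was 0.58 with all transcripts, 0.152 with Cyp2e1 left out of totals and score, and 0.156 with it left out of the totals only (95% bootstrap interval 0.039 to 0.237). In these sections its place in the score is unlikely to, since leaving it out of the score only gave 0.567 (0.445 to 0.648). Both intervals resample the 24 genes, all measured in the same sections, so they do not cover spread between sections. The share of Cyp2e1 in the totals is unlikely to be the whole cause for every gene, since 2 of the 24, Fads1 (0.83, adjusted p 0.0331) and Gstm2 (0.63, 0.033), still passed in limma with it left out of the totals (Benjamini-Hochberg over all 62 genes). What changed the correlation of these 2 stays open. Neither the rise of Gstm2 in transcript number nor any biological explanation was tested.

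Transcripts outside cells enter the positions but not the main comparisons of counts, and each of the 10 later sections had a larger share of them than both 0 h sections, up to 39.8% at 3 mo, with 60.2% to 71.0% in cells against 75.4% and 79.8% at 0 h. Fewer nuclei per tissue area could produce this, but the 1 relation computed cannot decide it. Over 12 sections the share in cells followed the number of cells per tile (Spearman rho 0.951, permutation p 6e-05, Pearson r 0.942, permutation p 8e-05). Pearson r was 0.863 without the 2 sections farthest from the median density, and rho was 0.929 within the 7 sections of slide 1. These measures are tied, because cells per tile multiplied by counts per cell gives the counts in cells per tile. Cells here are drawn outlines and nuclei were not counted, so fewer outlines need not mean fewer nuclei. Longer reach of hepatocyte transcripts could add to it, since the share in cells of 28 hepatocyte genes fell more than that of 8 genes of other cell types in 9 of 10 later sections, all but section 1 of 24 h. That count sits at the limit set for it, and of 14 ways of computing it 10 gave 9 or 10 while the 4 that kept only genes with 1000 transcripts gave 7 or 8, so it is weak. Both explanations stay open, and a biological difference between the times was not tested.

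The 2 sections at 0 h differed by more than 1 in log2(CPM + 1) in 21 genes, 17 of them lower in section 2. A slide difference may not be the whole cause: 72 h was also measured on slides 1 and 2. Over all 99 tested genes the slope of its difference on that at 0 h was 0.118 (95% bootstrap interval 0.035 to 0.188). The interval resamples genes, and with 1 pair of sections per time it does not cover spread between sections. The 72 h difference had the same direction in 18 of the 21 genes, so a smaller slide effect stays open. Apart from the slide the labels give no difference between these sections, and no biological explanation was tested.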

How the results depend on the processing

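Alternatives chosen after the results had been seen were the 14 d sections as 1 library, the total without Cyp2e1, and positions with Cyp2e1 left out of totals and score or of either alone.

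Over all alternatives, leaving out a section among them, named genes that were called kept direction and threshold in 2757 cases, lost the threshold in 584 and changed direction in 10. Named genes that were not called have no cases here, so a gain of the threshold cannot appear. Counts of genes stayed within 1.5 times in 357 cases, rose beyond it in 51 and fell below it in 87. These 10 changes of direction came with counts per cell: at 72 h Cyp2e1 (0.013), Cyp27a1 (0.086) and Cps1 (0.21), and at 14 d Glul (0.0024), Znrf3 (0.019), Cpox (0.13), C8b (0.33), Cps1 (0.46), Arg1 (0.46) and Lrp6 (0.69). Called genes outside the naming rule are not in these counts. Among them Vtn at 14 d (0.65 with counts per cell) and the position of Gstm2 at 48 h (-0.021 with Pearson correlation) changed direction, and other positions outside the rule were not followed. That scaling also gave 75 higher and 2 lower at 14 d, 32 and 2 at 48 h, 38 and 0 at 72 h (edgeR), 5 and 3 at 6 mo, and 2 lower at 24 h. Sections with more transcripts per cell become higher in it by construction.

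Total-count scaling gave 37 higher and 5 lower at 14 d, 40 and 2 at 48 h, 26 and 1 at 72 h, 1 higher at 3 mo, and 2 and 7 lower at 24 h and 6 mo. The total without Cyp2e1 gave 26 higher at 14 d and 4, 2, 1 and 3 lower at 24 h, 48 h, 72 h and 6 mo. DESeq2 gave 1 higher and 1 lower at 3 mo, 17 higher at 6 mo and 11 lower at 72 h. A minimum of 100 counts in every library, which tests fewer genes, gave 9 higher at 24 h and 1 at 3 mo, no filter 1 at 3 mo and 18 at 6 mo, and all transcripts 1 at 3 mo. The 24 h sections as 2 libraries gave 15 lower at 24 h and 1 higher at 3 mo, and only the times compared gave 3 lower at 48 h and 5 higher and 1 lower at 72 h. The 14 d sections as 1 library gave 9 higher and 2 lower at 24 h, 4 and 2 at 6 mo, 4 lower at 14 d and 39 over all times. With the slide as a block there were 6 higher and 2 lower at 24 h, 5 and 3 at 48 h, 2 lower at 72 h and 1 and 6 at 6 mo, and slide 1 only, with fewer sections, gave 8 higher at 24 h, 5 and 5 at 48 h and 4 and 1 at 72 h. Other than by construction, the cause was not tested.

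For positions, leaving Cyp2e1 out of totals and score gave 1 gene at 24 h, 2 at 48 h, 0 at 72 h, 0 at 14 d and 5 over all times (28 with it; limma). Leaving it out of the totals only gave 1, 2, 0, 0 and 4, and out of the score only 11, 21, 4, 13 and 28. Cells in place of tiles gave 4, 10, 1, 1, 0 and 3 from 24 h to 6 mo and 13 over all times. Tiles thinned to 50 transcripts gave 2, 9, 0, 1 and 0 from 24 h to 3 mo and 6 over all times. Tiles of 200 units gave 4 at 24 h, 1 at 72 h, 0 at 14 d and 3 mo and 18 over all times, and tiles of 800 units gave 8 at 72 h and 3 at 6 mo. Pearson in place of Spearman correlation gave 15 at 48 h, 1 at 3 mo and 4 at 6 mo. A score of Glul and Cyp2e1 against Pck1 gave 6 at 24 h, 7 at 14 d and 1 at 3 mo, the 24 h sections as 2 samples 18 at 24 h, and the slide as a block 0 at 3 mo. The cause was not tested.

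Leaving out each section gave these ranges. Higher and lower genes were 14 to 24 and 5 to 15 at 24 h, 9 to 22 and 7 to 17 at 48 h, 6 to 19 and 1 to 13 at 72 h, 14 to 26 and 10 to 23 at 14 d, 0 to 15 and 0 to 9 at 3 mo, and 9 to 20 and 9 to 22 at 6 mo, with 52 to 83 over all times. Genes with a moved position were 6 to 25 at 24 h, 15 to 36 at 48 h, 1 to 20 at 72 h, 0 to 34 at 14 d, 0 to 7 at 3 mo, 0 to 19 at 6 mo and 23 to 49 over all times.

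With the section number as a replicate block, 10 higher and 6 lower passed at 48 h, 9 and 5 at 72 h and 14 and 10 at 14 d, and 22, 1 and 11 genes by position. Deviations of same-numbered sections correlated at -0.51 to 0.207 between times. Equal numbers at 0 h and 72 h also mean the same slide (0.207 between these times), and no label pairs sections of different times.

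The scaling on general hepatocyte genes was not run, since the panel has none. The slide block leaves out 14 d, slide 1 only leaves out 14 d and 6 mo, and 3 mo and 6 mo have no value without their own section. Where 1 section of a time was left, it was assumed to vary like the other times. Genes with few counts, such as Ccna1 and Fzd2, allow only a fold against a floor or wide intervals at this depth.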
